A study of Mus musculus with 6 samples.

How the data were processed

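RNA was measured in frozen tibialis anterior of 6 samples, 3 WT and 3 KO, grouped by the genotype given in the labels. Libraries were made with a stranded total RNA kit that removes ribosomal RNA, per the labels' protocols. The submitters' processing notes name bcl2fastq 2.17.1.14, TopHat2 2.0.14, Bowtie with no version, HTSeq 0.6.1 and the mouse build mm9, without giving their roles, and the annotation and the strand setting of the counting are not given in the sources used here. The authors deposited 1 table of 28510 genes. It holds raw read counts per gene and library, not normalized, per the file headers. A second set of columns holds a signal that the authors normalized and divided by gene length in kb, per the file headers. Dividing the deposited counts by this signal and by median-of-ratios size factors gave 1 length per gene, with a relative spread between libraries of at most 3.82e-15. The authors' own comparison is deposited as a log2 fold change of KO over WT. It comes with the authors' p-value and adjusted p-value, and the test and tool behind them are not given in the sources used here. The deposited signal was used only to check the size factors and to obtain that gene length, and the authors' comparison only for the number of genes shared with it.

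The counts were used as deposited. Of the gene names, 14 had been turned into dates and were restored from their identifiers, and 939 repeated an earlier name and were made unique. No row lacked a gene identifier, and 26186 of the 28510 identifiers were found in a GENCODE mouse annotation of the GRCm38 build, which was used for symbols, gene types and GC content. No coordinates are given, because that build is not the authors'. Total counts ran from 35456883 to 102919416 per library. The floor for a gene without counts is 3 counts over the group and covers counting error only, and bootstrap intervals were drawn over the genes of a list (10000 draws). Such intervals take the genes as independent and leave out the spread between samples.

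KO and WT were compared with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr by group with a minimum count of 10 and a minimum total of 15, quasi-likelihood F test without robust estimation, no covariate), which kept 16628 genes. Adjusted p-values are Benjamini-Hochberg values over all genes tested, and genes at an adjusted p below 0.05 are said to have risen or fallen. The SE of a log2 fold change was its size divided by the square root of F. Levels per group are TMM-scaled CPM, as mean ± SD of 3 libraries. Gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, with camera at an estimated correlation, and with fry, each adjusted over the 43 lists. Of 999 list symbols, 989 were found. The labels name the samples as replicates and do not say that each came from its own animal, so p-values measure the spread between these samples. The groups, the test, the gene lists, the rule for naming genes and the alternatives other than those said to be added later were chosen before the data were examined.

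The genes named in the text are both targeted genes, the 8 largest rises and the 8 largest falls among called protein-coding or otherwise named genes with a mean log2 CPM of at least 1 and no overlap between groups, and the 5 lowest p among other called genes in each direction. Up to 4 members per list with the lowest p and the markers Cdkn1a, Gdf15, Chrna1, Myh4, Myh7, Col1a1, Pdgfra, Cd68 and Pax7 were named as well. Of the genes this rule takes, 1 is not reported here. Genes in the closing section that fall outside this rule were chosen after their values were seen.

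The fit was tested on simulated counts with the real means, dispersions and library sizes, in which 200 genes were changed. For KO against WT, edgeR recovered 75% of the genes changed by log2 1 and 100% of those changed by log2 2 among 16214 genes tested, and called 13 unchanged genes. Alternatives were other size factors, other expression filters, DESeq2 1.42.0, limma-voom, robust dispersion estimation, the replicate number as a block, mitochondrial and haemoglobin genes left out, and each library left out. Alternatives added after the data were seen were WT replicate 2 and KO replicate 1 left out together, library size alone, removal of a lowess trend (span 0.3) on GC content and length, thinning, and removal of genes high in WT replicate 2. Figures were drawn with matplotlib 3.10.9.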

Results

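Whole tibialis anterior, a muscle of the lower leg, of C57BL/6 mice at 12 months of age was profiled by RNA sequencing in 6 samples. All 6 carried floxed or deleted alleles of both genes that encode the histone variant H2A.Z, H2afz (H2A-Z.1) and H2afv (H2A-Z.2). The 3 WT samples had floxed alleles without Cre, and the 3 KO samples lacked both genes through Cre driven by the human skeletal actin (HSA) promoter, which is active in muscle fibres. The comparison asked how the loss of H2A.Z changed transcription in skeletal muscle. The 3 WT libraries held 88477775, 35456883 and 75814997 counts and the 3 KO libraries 88392143, 62318774 and 102919416. Mitochondrial genes took 22.2% ± 2.94 of the counts in WT and 25.3% ± 5.93 in KO, and Ttn, which encodes the giant sarcomere protein titin, took 11.8% ± 1.08 and 9.99% ± 0.970 (mean ± SD, n = 3 each).

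Both targeted genes were low in every KO library. H2afz stood at 16.5 ± 1.75 CPM in WT and 4.60 ± 0.514 CPM in KO, and H2afv at 18.6 ± 2.42 CPM in WT and 4.14 ± 0.405 CPM in KO (SD, n = 3 each). H2afz fell 3.59-fold (log2 fold change -1.85, SE 0.16, adjusted p = 4.42e-05 by edgeR with Benjamini-Hochberg adjustment), from 557 to 1509 counts per WT library to 269 to 525 per KO library. H2afv fell 4.50-fold (log2 fold change -2.17, SE 0.16, adjusted p = 2.42e-05 in the same edgeR fit), from 560 to 1558 counts to 245 to 487. The samples were whole muscle, which also holds cells other than fibres, and the counts covered each gene as a whole. Which exons were deleted is not given in the sources used here.

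**Figure D1:**
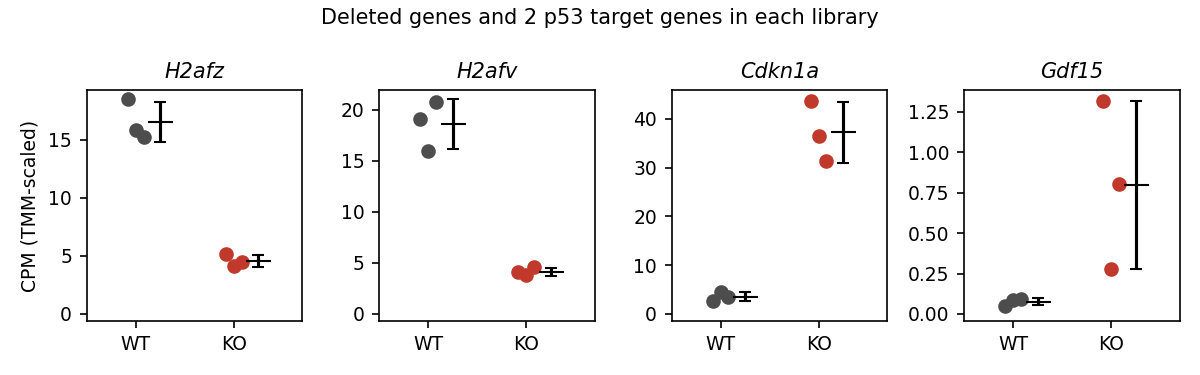
Expression of the deleted genes H2afz and H2afv and of the p53 target genes Cdkn1a and Gdf15 in each library, in CPM (counts scaled to library size) with TMM factors. Points are libraries, and the bar with whiskers is the mean ± SD of 3 libraries. All 3 KO libraries lay below the WT libraries for H2afz and H2afv and above them for Cdkn1a and Gdf15.

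KO muscle differed broadly from WT muscle, and the 6 gene lists with the most risen members were those of macrophage markers, embryonic and regenerating fibres, denervation, immediate early genes, senescence-associated genes and the neuromuscular synapse. Of 16628 genes tested, 2249 rose and 2062 fell in KO, 25.9% in all, and 1320 of the risen and 547 of the fallen genes changed at least 2-fold. The groups did not overlap for 42.6% of the genes tested, against 10% by chance for 3 libraries against 3. In the first principal component, which held 61.4% of the variance, the 3 KO libraries lay apart from the 3 WT libraries. The authors' deposited table called 2067 genes up and 2079 down at its own adjusted p, of which 1980 and 1965 rose and fell here, with 0 in the opposite direction. Risen genes made up 52.2% of the calls with TMM scaling and 76.8% (3418 risen, 1030 fallen) with library size alone, which moved the median log2 fold change of all genes from 0.01 to 0.22. Fold changes are given relative to the TMM scale, and the numbers of calls depended on single libraries. Without KO replicate 1, 1391 genes rose and 1168 fell, and without WT replicate 3, 1477 rose and 1395 fell. Without WT replicate 1, 2767 genes passed, of which 1533 rose.

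The gene with the lowest p among those that rose was 2410137F16Rik (log2 fold change 4.48, SE 0.20, adjusted p = 2.17e-06 by edgeR), named Srrm4os in the reference annotation. It is an antisense transcript, and its reads could not be told from those of its partner gene, since the strand setting of the counting is not given in the sources used here. Next came Myom3, which encodes an M-band protein of the sarcomere, at 3.40 (SE 0.17) and Ncam1, a cell adhesion molecule that spreads over denervated fibres, at 3.40 (SE 0.17). Golga7b and 4933415F23Rik followed at 3.45 (SE 0.19) and 3.16 (SE 0.17). The largest rises among expressed genes included Pkhd1, known for its role in polycystic kidney disease, at 6.01 (SE 0.49), the potassium channel subunit gene Kcne1l at 5.74 (SE 0.39), and Nup62cl at 5.27 (SE 0.48), each with at most 19 counts in a WT library. Sln, which encodes the calcium pump inhibitor sarcolipin, rose 38.7-fold, from 3.47 ± 1.13 CPM in WT to 136 ± 41.0 CPM in KO. Ankrd1, a stress-responsive titin-binding protein gene, rose 25.0-fold, from 10.8 ± 3.40 CPM in WT to 273 ± 64.6 CPM in KO (SD, n = 3 each). Tmem8c, which encodes the myoblast fusion protein myomaker, rose by log2 4.40 (SE 0.50). The antibody genes Ighg2b and Igkc rose by 6.75 (SE 1.15) and 4.73 (SE 0.77) with a wide spread, at 8.95 ± 8.49 and 9.72 ± 7.57 CPM in KO. Reads can be shared among such gene segments, and the Ighg2b call was lost with robust dispersion estimation.

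Among the genes that fell furthest were 1700001O22Rik at -4.18 (SE 0.21) and Dach2, a transcriptional repressor that links innervation to synaptic gene expression, at -3.24 (SE 0.28). Cd27, a receptor of the tumour necrosis factor family, had a log2 fold change of -3.20 (SE 0.51) from a WT level that itself spread widely, 9.29 ± 8.22 CPM. Samd10, 2610019F03Rik, 0610040J01Rik and the synaptotagmin gene Syt3 fell with log2 fold changes of -3.15 (SE 0.22), -2.97 (SE 0.26), -2.80 (SE 0.21) and -2.86 (SE 0.24). Wnk3-ps, at -3.15 (SE 0.24), bears a pseudogene name in the table, while the reference annotation names the same identifier Wnk3. Of the fallen genes with the lowest p, Plekhb1 had a log2 fold change of -2.48 (SE 0.17), the kinase gene Nek6 -2.01 (SE 0.15), the glutathione transferase gene Gstm5 -2.00 (SE 0.15), the kinesin gene Kif3c -1.96 (SE 0.16) and the vesicle protein gene Syngr1 -2.22 (SE 0.18).

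Of 43 gene lists, camera with its preset correlation called 16 up and 8 down, against 0 with an estimated correlation, where the lowest adjusted p was 0.412. The directional test fry, which does not compare a list with other genes, called 12 up and 3 down. Camera but not fry called the macrophage, matrix, adipocyte, tendon, endothelial, interferon, fast fibre, glycolysis, fatty acid oxidation, mitochondrial biogenesis, proteasome and ribosomal lists. Their fry adjusted p ran from 0.0511 (macrophage) to 0.432 (ribosomal). In the other splits of the 6 libraries into 3 and 3, camera called 11 to 20 lists and fry called 0, so the counts of members that passed the edgeR test are given with each camera p. Of all 16628 genes tested, 2249 rose and 2062 fell, 25.9% in all. A list count near or under these shares does not set the list apart.

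**Figure D2:**
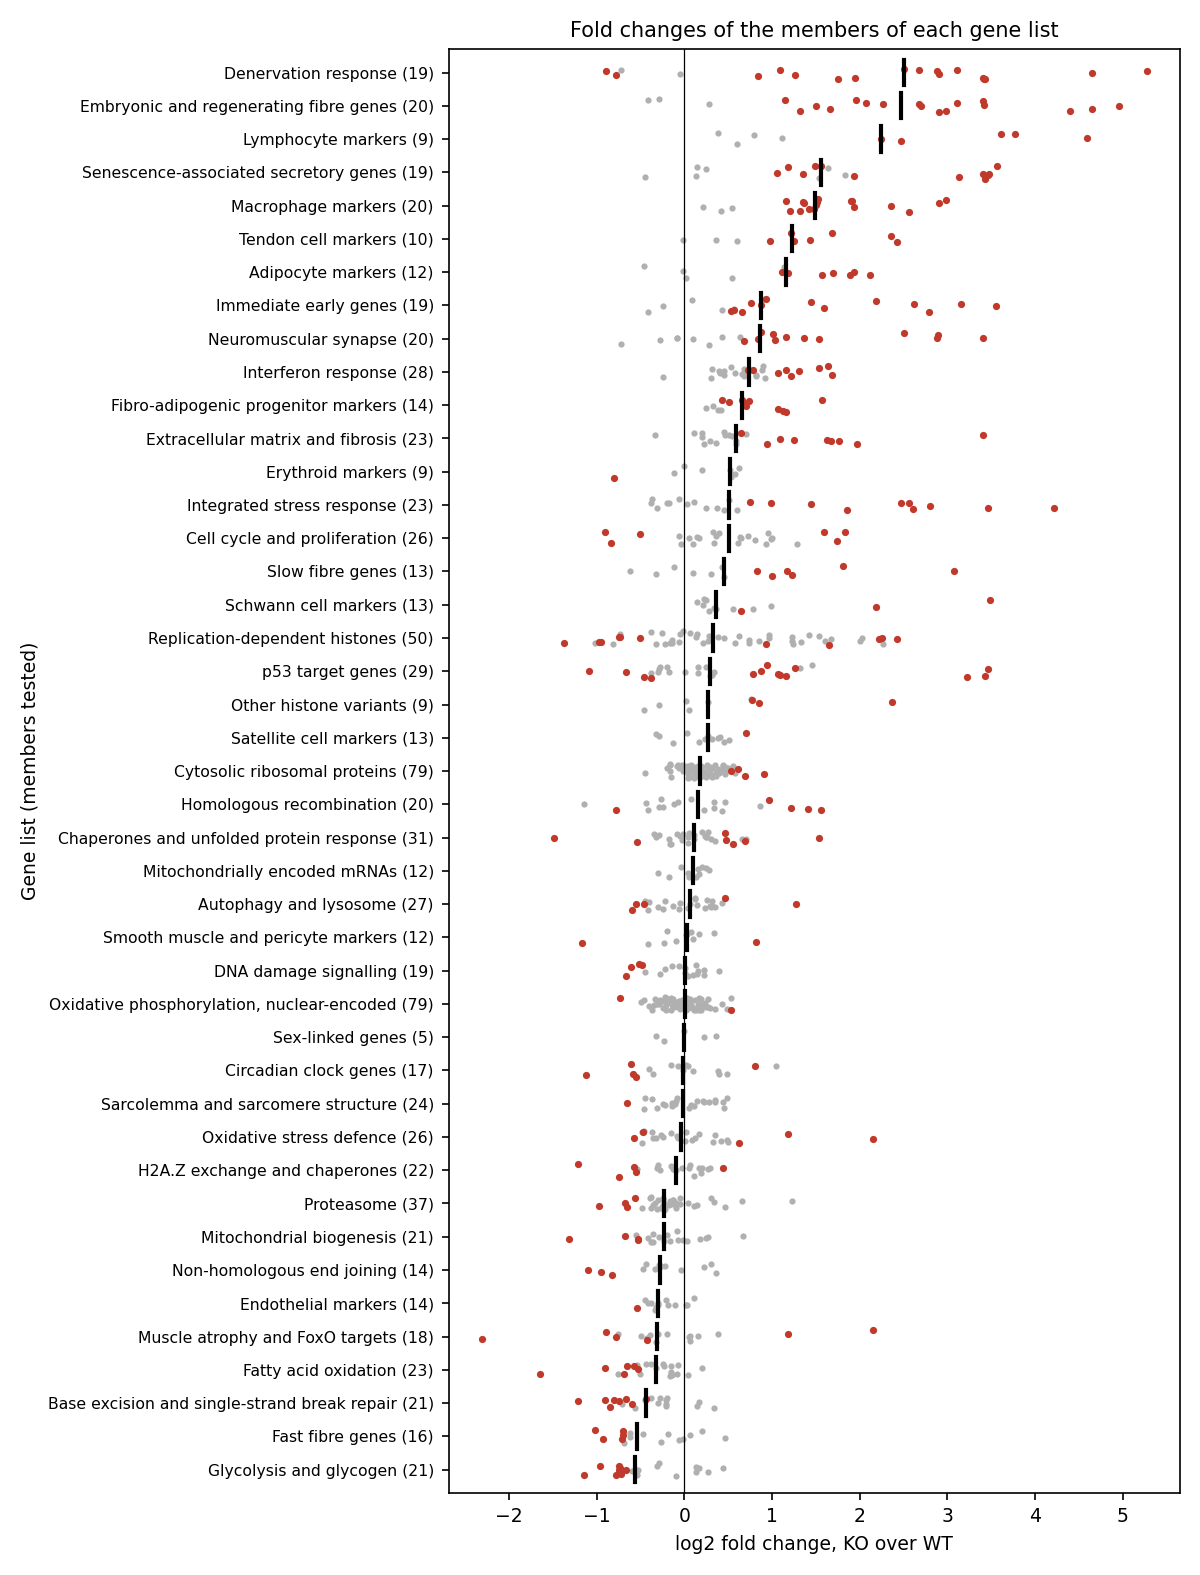
Log2 fold change (KO over WT) of every tested member of the 43 gene lists, ordered by median. The number of tested members follows each name. Red points passed the edgeR test at an adjusted p of 0.05, grey points did not, and black bars are list medians. Medians ran from -0.56 for glycolysis and glycogen genes to 2.51 for denervation response genes, on the TMM scale.

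Genes known to rise when a muscle loses its nerve supply were among the most changed. In the denervation list, 15 of 19 members rose and 2 fell (15 risen and 3 fallen adjusted over the list alone), with a median log2 fold change of 2.51 (camera adjusted p = 1.02e-07, and adjusted p = 0.412 with an estimated correlation). Its member Chrna1, a subunit gene of the muscle acetylcholine receptor, rose with a log2 fold change of 2.51 (SE 0.16). The myogenic regulator Myog rose from 2.68 ± 0.524 CPM in WT to 16.9 ± 1.80 CPM in KO. The 2 members that fell, Trim63 and Fbxo32, encode ubiquitin ligases of muscle atrophy, with log2 fold changes of -0.78 (SE 0.15) and -0.89 (SE 0.20). Among neuromuscular synapse genes, 12 of 20 rose and 0 fell (14 risen and 1 fallen adjusted over the list alone), at a median of 0.86 (camera adjusted p = 1.52e-05, and adjusted p = 0.412 with an estimated correlation). Besides Chrna1, the risen synapse genes included the receptor subunit genes Chrnd at 2.88 (SE 0.25) and Chrne at 2.89 (SE 0.16). Schwann cell markers, from the cells that wrap motor axons, had 3 of 13 risen (4 adjusted over the list alone; camera adjusted p = 0.00415, and adjusted p = 0.528 with an estimated correlation). They were Gldn at 3.49 (SE 0.42), the transcription factor gene Egr2 at 2.19 (SE 0.40) and the myelin gene Pmp22 at 0.64 (SE 0.15). Mbp, another myelin gene, had a log2 fold change of 0.55 (SE 0.19) with adjusted p = 0.0523 by edgeR.

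Genes of embryonic and regenerating fibres rose in 17 of 20 cases with 0 fallen (17 risen and 0 fallen adjusted over the list alone), at a median of 2.47 (camera adjusted p = 1.95e-10, and adjusted p = 0.412 with an estimated correlation). The list shared 6 tested members with the denervation list, among them Ncam1, Ankrd1 and Myog, and its members Igf2, a fetal growth factor gene, and Tmem8c rose by log2 2.07 (SE 0.15) and 4.40 (SE 0.50). Satellite cell markers, which mark the stem cells of muscle, had 1 of 13 risen, Cxcr4 at 0.71 (SE 0.20), and 0 adjusted over the list alone. With 1 library omitted, risen satellite cell markers numbered 0 in edgeR without WT replicate 1, WT replicate 2 or KO replicate 1, 2 without KO replicate 3 and 4 without KO replicate 2. Pax7, their defining transcription factor gene, stood at 0.17 (SE 0.20) with adjusted p = 0.578 by edgeR. Slow fibre genes rose in 6 of 13 cases (6 risen and 0 fallen adjusted over the list alone). Their median was 0.45 (camera adjusted p = 0.013, and adjusted p = 0.412 with an estimated correlation). They were led by the slow troponin genes Tnni1 and Tnnt1 at 3.08 (SE 0.29) and 1.81 (SE 0.21) and the slow calcium pump gene Atp2a2 at 1.00 (SE 0.13). Myh7, the slow myosin heavy chain gene, stood at 0.93 ± 0.44 CPM in KO and did not pass (log2 fold change 0.45, SE 0.35, adjusted p = 0.385 by edgeR). Fast fibre genes fell in 5 of 16 cases (8 adjusted over the list alone). Their median was -0.55 (camera adjusted p = 0.00538, and adjusted p = 0.528 with an estimated correlation). They included the tropomyosin gene Tpm1 at -1.02 (SE 0.21) and the myosin-binding protein gene Mybpc2 at -0.93 (SE 0.22). Myh4, the fast IIb myosin gene, had a log2 fold change of -0.68 (SE 0.25) with adjusted p = 0.0688 by edgeR. With each library omitted in turn, risen members numbered 14 to 15 in the denervation list, 9 to 13 in the synapse list, 17 to 18 in the embryonic list and 5 to 6 in the slow list. Only 1 fast fibre gene fell without WT replicate 1 or KO replicate 1, 2 without WT replicate 3 and 3 without KO replicate 2. Without KO replicate 3 the camera call of the slow list was lost, at adjusted p = 0.0594.

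**Figure D3:**
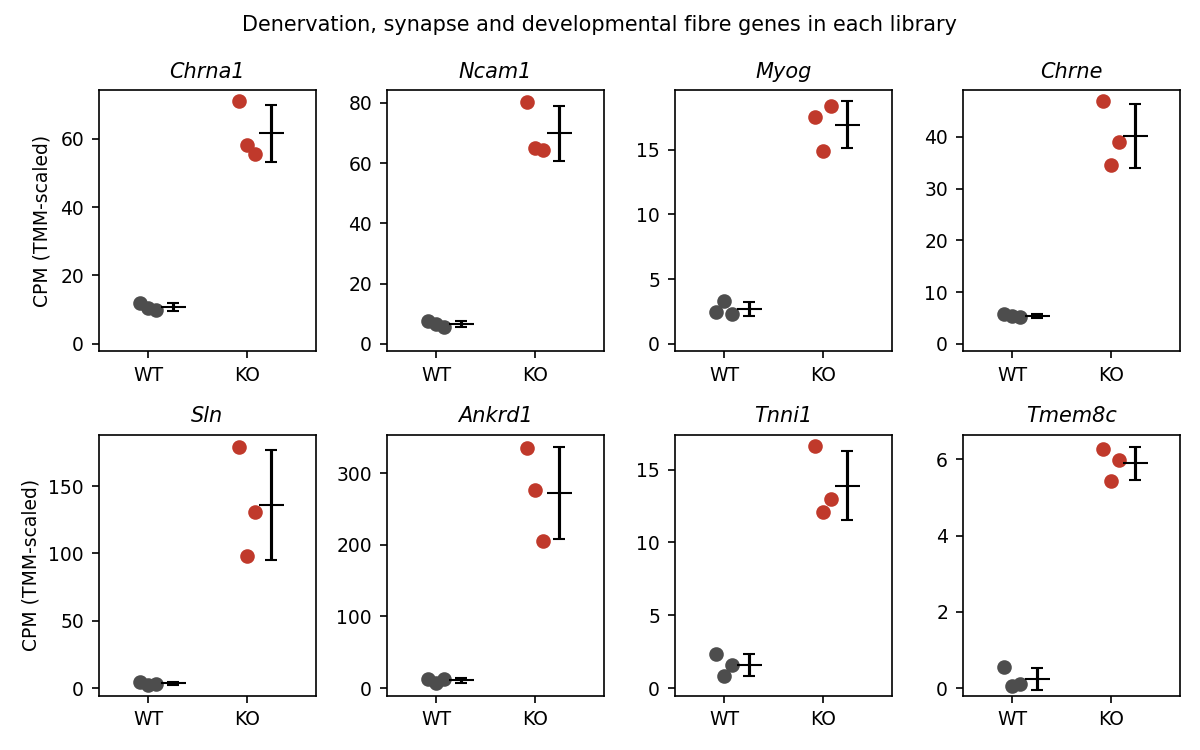
Expression of 8 genes of denervated, synaptic, slow or developing fibres in each library, in TMM-scaled CPM. Points are libraries, and the bar with whiskers is the mean ± SD of 3 libraries; all 3 KO libraries lay above all WT libraries for each gene.

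Energy metabolism genes were lower in part. Glycolysis and glycogen genes fell in 9 of 21 cases with 0 risen (12 fallen adjusted over the list alone). Their median was -0.56 (camera adjusted p = 0.00163, and adjusted p = 0.528 with an estimated correlation). They included Phka1, a subunit of phosphorylase kinase, at -1.14 (SE 0.22) and Pfkm, the muscle phosphofructokinase gene, at -0.97 (SE 0.23). Fatty acid oxidation genes fell in 6 of 23 cases (7 adjusted over the list alone). Their median was -0.32 (camera adjusted p = 0.00185, and adjusted p = 0.528 with an estimated correlation). Examples were Ucp3, a mitochondrial uncoupling protein gene, at -1.64 (SE 0.34) and Acads, a short-chain acyl-CoA dehydrogenase gene, at -0.90 (SE 0.15). Mitochondrial biogenesis genes fell in 4 of 21 cases (4 adjusted over the list alone; camera adjusted p = 0.044, and adjusted p = 0.653 with an estimated correlation). Examples were the mitochondrial DNA packaging factor gene Tfam at -0.53 (SE 0.13) and the fission gene Fis1 at -0.68 (SE 0.18). Nuclear-encoded oxidative phosphorylation genes had 1 risen, Cox8a at 0.53 (SE 0.17), and 1 fallen, Ndufs4 at -0.73 (SE 0.16), of 79 (0 adjusted over the list alone, median 0.01), and 0 of 12 mitochondrially encoded mRNAs passed in edgeR (median 0.10), 0 at an unadjusted p under 0.05 and 0 by DESeq2 or limma-voom. Without WT replicate 2, camera called the nuclear-encoded list down (adjusted p = 0.0472, and adjusted p = 0.690 with an estimated correlation), and 3 of its genes fell, as many as without KO replicate 2. With each library omitted in turn, fallen glycolysis genes numbered 1 to 9, with 1 without WT replicate 1, 5 without WT replicate 3, 3 without KO replicate 1 and 5 without KO replicate 2. Fallen fatty acid oxidation genes numbered 3 without WT replicate 2 and 2 without KO replicate 1, fallen biogenesis genes 1 without WT replicate 1 and 2 without KO replicate 1, and the call of the biogenesis list was lost without WT replicate 1, KO replicate 1 or KO replicate 2. That call was also lost with a stricter expression filter, library size alone, the GC and length trend removed, thinning, and WT replicate 2 and KO replicate 1 both left out, 8 of 17 alternatives in all, with adjusted p of 0.00431 to 0.152 over the 17.

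Genes of the p53 response rose in part. Of 29 p53 targets, 10 rose and 4 fell (10 risen and 5 fallen adjusted over the list alone), with a median of 0.30. The list was not called by camera (adjusted p = 0.0596, and adjusted p = 0.474 with an estimated correlation) and was called by fry (adjusted p = 0.00577). Camera called it without WT replicate 2, at adjusted p = 0.0396, and adjusted p = 0.540 with an estimated correlation. Cdkn1a, the cell cycle inhibitor p21, rose 10.8-fold, from 3.51 ± 0.937 CPM in WT to 37.2 ± 6.24 CPM in KO (SD, n = 3 each, adjusted p = 8.77e-06 by edgeR). Gadd45a and Plk2, a growth arrest gene and a kinase gene, rose by log2 1.26 (SE 0.18) and 0.94 (SE 0.14), and Gdf15, a stress cytokine gene, by 3.46 (SE 0.62) from 3 to 6 counts per WT library to 18 to 134 per KO library. Polk, a translesion DNA polymerase gene, had a log2 fold change of -1.08 (SE 0.18). Fallen p53 targets numbered 1 without any single WT library or KO replicate 1, and 2 without KO replicate 3. Genes of the senescence-associated list rose in 12 of 19 cases with 0 fallen (15 risen and 0 fallen adjusted over the list alone), at a median of 1.56 (camera adjusted p = 6.25e-06, and adjusted p = 0.412 with an estimated correlation). Besides secretory genes, the list holds the cell cycle inhibitor genes Cdkn1a, which is also in the p53 list, and Cdkn2a. Cdkn2a rose by log2 3.14 (SE 0.41), the growth factor binding protein gene Igfbp5 by 1.50 (SE 0.17) and the protease inhibitor gene Timp1 by 3.40 (SE 0.54). Macrophage markers rose as well (17 of 20), and several secretory genes are also made by such cells.

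DNA repair genes moved in both directions. Base excision and single-strand break repair genes fell in 8 of 21 cases with 0 risen (9 fallen adjusted over the list alone). Their median was -0.43 (camera adjusted p = 0.00106, and adjusted p = 0.526 with an estimated correlation). Among them were the abasic site endonuclease gene Apex1 at -0.91 (SE 0.17), the glycosylase gene Neil1 at -0.85 (SE 0.19) and Parp2 at -0.66 (SE 0.15). Non-homologous end joining genes fell in 3 of 14 cases (3 adjusted over the list alone). Their median was -0.28 (camera adjusted p = 0.0215, and adjusted p = 0.474 with an estimated correlation). These were Xrcc5, which encodes Ku80, at -0.95 (SE 0.13), the polymerase gene Poll at -1.10 (SE 0.18) and Mad2l2 at -0.83 (SE 0.17). Homologous recombination genes rose in 4 of 20 cases and fell in 1 (4 risen and 1 fallen adjusted over the list alone; camera adjusted p = 0.655). Examples were Bard1, Dna2 and Brca1 at 1.22 (SE 0.35), 0.97 (SE 0.29) and 1.56 (SE 0.47) and Nbn, of the break-sensing MRN complex, at -0.78 (SE 0.17). DNA damage signalling genes fell in 4 of 19 cases (2 adjusted over the list alone; camera adjusted p = 0.354). These were Hus1 at -0.61 (SE 0.15), Rnf8 at -0.67 (SE 0.17), Atrip at -0.51 (SE 0.16) and Rad17 at -0.48 (SE 0.16). Without KO replicate 1, 4 base excision genes and 3 end joining genes fell. Recombination genes that rose numbered 0 in edgeR without WT replicate 1, WT replicate 3 or KO replicate 1 and 2 without any other single library. Damage signalling genes that fell numbered 0 in edgeR without WT replicate 1 or KO replicate 1 and 2 without WT replicate 3 or KO replicate 3. Base excision genes that fell numbered 4 without WT replicate 1 and 5 without WT replicate 2. The end joining call was lost with a stricter expression filter, at adjusted p = 0.0568.

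Markers of immune and connective tissue cells were higher in KO muscle, while 0 of 14 endothelial markers rose in edgeR, 0 of them at an unadjusted p under 0.05 and 0 by DESeq2 or limma-voom. Macrophage markers rose in 17 of 20 cases (17 risen and 0 fallen adjusted over the list alone). Their median was 1.49 (camera adjusted p = 1.04e-07, and adjusted p = 0.528 with an estimated correlation). Examples were the protease gene Ctss at 2.91 (SE 0.34), Mpeg1 at 2.99 (SE 0.35), the antigen presentation gene Cd74 at 2.56 (SE 0.32), the leukocyte gene Ptprc at 1.91 (SE 0.25) and Cd68 at 1.51 (SE 0.36). Of 17 lymphocyte markers, 9 passed the expression filter, and 5 of these rose (5 adjusted over the list alone). A marker can pass that filter through KO counts alone, which favours rises. Cd4 did so, with 0 to 3 counts per WT library and 22 to 100 per KO library. The median of the 9 was 2.25 (camera adjusted p = 0.000625, and adjusted p = 0.412 with an estimated correlation). Risen markers included the T cell genes Cd2 at 2.48 (SE 0.35), Cd4 at 4.59 (SE 0.77) and Cd3g at 3.77 (SE 0.76). Cd3g had at most 39 counts in a library. Without KO replicate 1, 3 of 10 tested lymphocyte markers rose. Interferon response genes rose in 9 of 28 cases (11 adjusted over the list alone). Their median was 0.74 (camera adjusted p = 0.000514, and adjusted p = 0.577 with an estimated correlation). Among them were the sensor adaptor gene Tmem173 at 0.73 (SE 0.20) and Irf7 at 1.53 (SE 0.43). These rises depended on single libraries: 0 of 28 rose without KO replicate 1, where interferon genes were highest, 2 without WT replicate 2, 1 without WT replicate 1 or 3, and 15 without KO replicate 3. They depended on the test as well, with 9 risen by DESeq2 and 2 by limma-voom on all libraries. The Irf7 call was lost in 8 of 19 alternatives, among them DESeq2, limma-voom and robust dispersion estimation. With WT replicate 2 and KO replicate 1 both left out, 0 rose in edgeR and the camera call of the interferon list was lost, at adjusted p = 0.106.

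Extracellular matrix and fibrosis genes rose in 9 of 23 cases with 0 fallen (9 risen and 0 fallen adjusted over the list alone), at a median of 0.58 (camera adjusted p = 0.000357, and adjusted p = 0.528 with an estimated correlation), beside markers of several cell types of the connective tissue. Thbs1, Postn and Ctgf, secreted matrix proteins, rose by log2 1.97 (SE 0.28), 1.63 (SE 0.25) and 1.25 (SE 0.21), whereas Col1a1, a chain of type I collagen, stood at 0.58 (SE 0.29) with adjusted p = 0.162 by edgeR. Fibro-adipogenic progenitor markers rose in 10 of 14 cases (11 adjusted over the list alone; camera adjusted p = 0.000358, and adjusted p = 0.484 with an estimated correlation). Examples were Fbln1 at 1.57 (SE 0.25), the proteoglycan gene Dcn at 1.16 (SE 0.30) and the growth factor receptor gene Pdgfra at 0.66 (SE 0.22). Adipocyte markers rose in 7 of 12 cases (8 adjusted over the list alone; camera adjusted p = 0.00538, and adjusted p = 0.528 with an estimated correlation). They included the lipid droplet gene Plin1 at 1.93 (SE 0.32) and the leptin gene Lep at 2.12 (SE 0.53). Tendon cell markers rose in 7 of 10 cases (7 adjusted over the list alone; camera adjusted p = 0.00185, and adjusted p = 0.528 with an estimated correlation). They included Fmod at 1.69 (SE 0.30) and Kera at 2.43 (SE 0.55). Endothelial markers had 1 of 14 fallen, the water channel gene Aqp1 at -0.54 (SE 0.17), and 0 adjusted over the list alone (median -0.30, camera adjusted p = 0.0439, and adjusted p = 0.577 with an estimated correlation). Fallen endothelial markers numbered 3 without KO replicate 3 and 0 in edgeR without any other single library, and the endothelial call was lost without WT replicate 3 or KO replicate 1. It was also lost with a stricter expression filter, library size alone, thinning, and WT replicate 2 and KO replicate 1 both left out, 6 of 17 alternatives in all, with adjusted p of 0.0134 to 0.242 over the 17. Smooth muscle and pericyte markers had 1 risen, Cspg4 at 0.82 (SE 0.23), and 1 fallen, Cnn1 at -1.17 (SE 0.38), of 12 (0 adjusted over the list alone). Erythroid markers had 1 of 9 fallen (1 adjusted over the list alone), Bpgm at -0.81 (SE 0.14), and 0 risen in edgeR (2 at an unadjusted p under 0.05, 1 by DESeq2 and 0 by limma-voom). Without WT replicate 3, 4 erythroid markers rose, at a median of 0.90 (camera adjusted p = 0.0224, and adjusted p = 0.567 with an estimated correlation). With 1 library omitted, risen matrix genes numbered 7 to 14, with 14 without KO replicate 3, and risen tendon markers 4 without WT replicate 3. Risen progenitor markers fell to 5 without WT replicate 2, KO replicate 1 or KO replicate 2 and 4 without WT replicate 3, and risen adipocyte markers to 2 without KO replicate 2, 3 without WT replicate 1 and 4 without WT replicate 3.

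Integrated stress response genes rose in 10 of 23 cases (10 risen and 0 fallen adjusted over the list alone). Their median was 0.51 (camera adjusted p = 0.0029, and adjusted p = 0.528 with an estimated correlation). Examples were the amino acid synthesis genes Asns at 2.60 (SE 0.25) and Psat1 at 2.81 (SE 0.33), the folate enzyme gene Mthfd2 at 2.47 (SE 0.34) and the stress protein gene Nupr1 at 2.57 (SE 0.24). Immediate early genes, which also respond to handling of the tissue, rose in 13 of 19 cases (15 risen and 1 fallen adjusted over the list alone). Their median was 0.87 (camera adjusted p = 1.52e-05, and adjusted p = 0.412 with an estimated correlation). Examples were Fos at 2.62 (SE 0.22), Egr1 at 2.79 (SE 0.30), Junb at 1.60 (SE 0.18) and Atf3 at 1.44 (SE 0.21). Proteasome genes fell in 4 of 37 cases in edgeR (3 adjusted over the list alone), a smaller share than among all genes tested. Their median was -0.23 (camera adjusted p = 0.00951, and adjusted p = 0.528 with an estimated correlation). Psmd8, a subunit gene of the regulatory particle, had a log2 fold change of -0.98 (SE 0.18). Fallen proteasome genes numbered 9 by DESeq2 and 5 by limma-voom. The camera call of the proteasome list was lost with library size alone, at adjusted p = 0.0729. Ribosomal protein genes rose in 4 of 79 cases (1 adjusted over the list alone), a smaller share than among all genes tested. Their median was 0.17 (camera adjusted p = 0.0128, and adjusted p = 0.869 with an estimated correlation). Rpl3 rose by log2 0.91 (SE 0.17). Risen ribosomal genes numbered 1 to 13 with 1 library omitted, with 1 without WT replicate 1, WT replicate 2 or KO replicate 1, 7 without WT replicate 3 and 13 without KO replicate 2, and the call was lost without WT replicate 2, KO replicate 1 or both. Of 18 atrophy and FoxO target genes, 4 fell and 2 rose (2 risen and 5 fallen adjusted over the list alone; camera adjusted p = 0.11, and adjusted p = 0.047 without KO replicate 2, where it was adjusted p = 0.616 with an estimated correlation). Mstn, which encodes the growth inhibitor myostatin, fell 4.96-fold (log2 fold change -2.31, SE 0.22), and the metallothionein genes Mt1 and Mt2 rose by log2 1.19 (SE 0.36) and 2.15 (SE 0.54), calls that were lost without KO replicate 1 and with robust dispersion estimation. Chaperone and unfolded protein response genes had 5 risen and 2 fallen of 31 (5 risen and 2 fallen adjusted over the list alone), with Hspb7 at 1.53 (SE 0.21) and Hsph1 at -1.49 (SE 0.23). Risen chaperone genes numbered 1 without WT replicate 1, 3 without WT replicate 2 and 2 without WT replicate 3 or KO replicate 1.

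Among the 22 genes of H2A.Z exchange and its chaperones, 4 fell and 1 rose (1 risen and 4 fallen adjusted over the list alone), and camera did not call the list (adjusted p = 0.281), whereas fry called it down (adjusted p = 0.0393). The fry call was lost without any single library other than WT replicate 3. The H2A.Z chaperone gene Vps72 fell 2.31-fold (log2 fold change -1.21, SE 0.14, adjusted p = 0.000218 by edgeR), and Dmap1, Kat5 and Ruvbl1, members of the exchange complexes, had log2 fold changes of -0.74 (SE 0.16), -0.55 (SE 0.14) and -0.58 (SE 0.18). Without KO replicate 1, or without WT replicate 3, 2 members fell, and with library size alone 2 fell and 2 rose. Other histone variant genes had 3 of 9 risen (4 risen and 1 fallen adjusted over the list alone; camera adjusted p = 0.197, fry adjusted p = 0.00457). They were H3f3b, which encodes histone H3.3, at 0.77 (SE 0.15), the linker histone gene H1fx at 2.37 (SE 0.52) and the centromere histone gene Cenpa at 0.85 (SE 0.25). H1fx had only 2 to 8 counts per WT library and 16 to 46 per KO library. The Cenpa call was lost in 5 of 19 alternatives, with adjusted p up to 0.0918 by edgeR. Replication-dependent histone genes, many of them near-identical copies whose reads can be shared, had 5 risen and 6 fallen of 50 (5 risen and 5 fallen adjusted over the list alone; camera adjusted p = 0.317). Hist1h4i had the lowest p, at -1.38 (SE 0.18), and risen counts ran from 1 to 11 with 1 library omitted, the lowest without WT replicate 3 or KO replicate 1 and the highest without KO replicate 3. They numbered 2 without WT replicate 2 and 9 without KO replicate 2, and 3 fell without WT replicate 3.

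Cell cycle genes split, with 3 risen and 3 fallen of 26 (3 risen and 3 fallen adjusted over the list alone; camera adjusted p = 0.169). Rrm2 and Bub1b stood at 1.83 (SE 0.31) and 1.74 (SE 0.37), and Mcm2 and Aurka at -0.90 (SE 0.17) and -0.84 (SE 0.19). Without WT replicate 2, camera called the cell cycle list up (adjusted p = 0.00909, and adjusted p = 0.632 with an estimated correlation). Circadian clock genes had 4 fallen and 1 risen of 17 (4 risen and 5 fallen adjusted over the list alone; camera adjusted p = 0.655), with Nfil3 at -1.12 (SE 0.20) and Nr1d1 at 0.81 (SE 0.20). Autophagy and lysosome genes had 2 risen and 3 fallen of 27 (2 risen and 2 fallen adjusted over the list alone). Examples were Gpnmb, a lysosomal glycoprotein gene of macrophages, at 1.28 (SE 0.19) and the autophagy kinase gene Ulk1 at -0.55 (SE 0.15). Oxidative stress defence genes had 3 risen and 2 fallen of 26 (3 risen and 2 fallen adjusted over the list alone), with Gstp1 at -0.57 (SE 0.13). Sarcolemma and sarcomere genes had 1 of 24 fallen, Myot at -0.65 (SE 0.17), and 0 adjusted over the list alone, while without KO replicate 2, 5 rose and 1 fell. Without WT replicate 1, 1 clock gene, 0 autophagy genes and 1 cell cycle gene fell in edgeR. Fallen autophagy genes also numbered 0 without WT replicate 3 or KO replicate 1, and fallen clock genes 2 without KO replicate 1 and 1 without KO replicate 3. Risen autophagy genes numbered 4 and risen clock genes 3 without KO replicate 2. Without KO replicate 1, 0 oxidative stress genes rose, and without KO replicate 3, 5 cell cycle genes rose. With library size alone, clock genes had 4 risen and 1 fallen, oxidative stress genes 6 risen and 0 fallen, and sarcolemma and sarcomere genes 3 risen and 0 fallen. Of 5 sex-linked genes, 0 passed in edgeR, adjusted over the list alone or unadjusted at 0.05, and 0 by DESeq2 or limma-voom. Xist, which is expressed from an inactive X chromosome, had 3 to 15 counts per library while the Y-linked gene Ddx3y had 2411 to 6830.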

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

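The alternatives that leave out WT replicate 2 and KO replicate 1 together, use library size alone, remove a GC and length trend, thin the counts or leave out genes high in WT replicate 2 were chosen after the data were seen. H2afz and H2afv fell under all alternatives that were run, with log2 fold changes of -1.97 to -1.63 and -2.27 to -1.95. No called gene changed to a call in the other direction in any of them. The counts stayed within 1.5 times their value with other size factors, other filters, DESeq2, limma-voom, robust dispersion, mitochondrial and haemoglobin genes or genes high in WT replicate 2 left out, the GC and length trend removed, and thinning. With each library left out in turn, risen genes numbered 1391 to 2321, fallen genes 1168 to 2189 and all calls 2559 to 4510. The lowest values came without KO replicate 1. Without WT replicate 1, 2767 genes passed, of which 1533 rose, and without WT replicate 3, 1477 rose and 1395 fell (2872 in all). Fewer samples give the test less power, and the cause was not tested further. With WT replicate 2 and KO replicate 1 both left out, 1113 genes rose and 977 fell, 2090 in all, and the median of the ribosomal protein list changed sign, to -0.016. Library size alone gave 3418 risen and 1030 fallen genes, and moved the median log2 fold change of all genes from 0.01 to 0.22. A fold of at least 2 as well left 1320 risen and 547 fallen, 1867 in all. The replicate block gave 2457 risen and 2236 fallen genes and 24 called lists, and changed no direction. The deviations of same-numbered samples from their group means correlated at 0.06, 0.02 and 0.06 for replicates 1, 2 and 3, so the numbers were not taken to pair the samples. WT replicate 2 correlated best with KO replicate 1 and not with its own number. Of 24 lists called by camera, 17 kept the call in every alternative that retested them, and the number called ran from 20 to 26. Of all 43 lists, 0 were called with an estimated correlation and 15 by fry. Those 15 were not all camera calls, since they included the p53 target, H2A.Z exchange and other histone variant lists, which camera did not call. Of 166 called named genes, 97 kept the call throughout. Sex was not run as a covariate, because all 6 libraries showed Y-linked counts and almost no Xist. In the simulated counts, where only 200 genes were changed and none of them weakly expressed, 75% of genes changed by log2 1 were called. In the real comparison 25.9% of genes passed, so that share need not hold here, and small changes may be missed.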

Other observations

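The lists of germ cell, liver, brain, interferon gamma, imprinted and immunoglobulin genes and the tests on them, the count of olfactory receptor genes, the count of falls shared without WT replicate 2, and the comparison of macrophage with endothelial markers, were chosen only after the data were seen. The genes named below were picked after their values were seen. Several imprinted genes, which are expressed from 1 parental allele and many of which act in fetal growth, differed in KO muscle. Of 31 imprinted genes tested, 3 of the list being also in the embryonic fibre list, 10 rose and 4 fell (11 and 4 adjusted over the list alone; camera adjusted p = 0.0357, and adjusted p = 0.50 with an estimated correlation). Without KO replicate 1, 10 rose and 2 fell. Igf2 and H19, neighbours under shared control, rose with log2 fold changes of 2.07 (SE 0.15) and 1.15 (SE 0.23), Peg3 rose by 1.94 (SE 0.16) and Zdbf2 by 2.32 (SE 0.19). Slc38a4, an amino acid transporter gene, and Asb4 had log2 fold changes of -1.93 (SE 0.24) and -1.34 (SE 0.16). Risen genes made up 32.3% of the list against 13.5% of the other genes tested (Fisher's exact test, two-sided, p = 0.00596, with genes not being independent). Because the list was written after the values were seen, a joint rise of imprinted genes is a hypothesis only.

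Antibody genes were higher in every KO library than in any WT library for several segments. Igkc had 5 to 29 counts per WT library and 1817, 185 and 903 in KO replicates 1, 2 and 3, and Igj, the joining chain gene of plasma cells, had 11 to 25 and 226 to 790. Of 6 genes tested in the immunoglobulin list, which holds Igj besides constant genes, 4 rose and 0 fell in edgeR (5 and 0 adjusted over the list alone, camera adjusted p = 0.0152, and adjusted p = 0.466 with an estimated correlation). The constant genes Ighm, at -0.33 (SE 0.29), and Ighg2c, at 1.12 (SE 0.48), did not pass (adjusted p = 0.429 and 0.109 by edgeR). Arhgap36 had 0 counts in all 3 WT libraries and 99 to 254 per KO library, at least 129-fold higher against a floor of 3 counts over the WT group. The small RNA gene mmu-mir-689-2 had 69028 counts in KO replicate 2 and 1889 to 4630 in the other libraries.

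KO and WT muscle differed in 4311 genes (2249 risen, 2062 fallen). Thinning all libraries to the lowest size factor left 3965 calls, and removing a trend on GC content and length gave 5233, which argues against depth and against that trend as the whole source. A uniformly lower share of muscle fibres would raise the markers of other cell types alike. The median of the macrophage markers instead exceeded that of the endothelial markers by 1.79 (bootstrap 95% interval 1.54 to 2.21). That interval takes the genes as independent and leaves out the spread between samples. These lists were compared after their values were seen, so the difference speaks only against a uniform shift. Medians were 2.25, 1.23, 1.16, 0.66 and 0.37 for lymphocyte, tendon, adipocyte, progenitor and Schwann cell markers. They were 0.52, 0.26 and 0.03 for erythroid, satellite cell and smooth muscle markers. The lymphocyte median covered only the 9 of 17 markers that passed the expression filter, some of them through KO counts alone. Of 10 splits of the libraries into 3 and 3, 1, the real one, gave as many calls (highest other 2), risen genes (highest other 2 in either direction) and fallen genes (highest other 2), and 1 gave as many called lists (24, highest other 20), and 10 splits cannot give a share under 0.05. Transcripts of immune cells alone are argued against as the whole source by the fibre genes. Of 20 embryonic and regenerating fibre genes 17 rose, at a median of 2.47, and 17 to 18 rose with any 1 library omitted. Open are the genotype, a changed mix of cell types, a change in the immune cells for part of the calls, and any difference between the groups in handling, on which the labels give nothing.

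WT replicate 2 held transcripts of genes known from testis germ cells, and 665 genes were over 4 times higher in it than in every other library, among them the protamine gene Prm2 (224 counts there and 0 to 1 elsewhere) and the sperm genes Ldhc and Smcp (198 and 128 counts against at most 1). Over 40 germ cell genes, of which 7 passed the expression filter in these muscles, 82.5% were highest in WT replicate 2 at a median log2 ratio of 4.37 to the next library, while the higher of the liver and brain lists stood at -0.87; RNA of testis in that library is a candidate source. Genomic DNA is argued against by 48 olfactory receptor genes with a read after thinning to the lowest size factor, against 63 to 86 in the others (48 against 59 to 102 after thinning to the lowest total count), and how such RNA entered was not tested. Of the fallen genes, 1 of 2062 (0.0485%) was over 4 times higher in WT replicate 2 than in every other library, which decides nothing, because the WT spread of such a gene works against a call. Without WT replicate 2, 1564 of the 2062 (75.8%) were still called as fallen, which argues against that RNA as the source of most of the falls. Omission of WT replicate 1, WT replicate 3, KO replicate 1 or KO replicate 3 kept fewer, 1192, 1340, 1150 and 1544. Omission of KO replicate 2 kept 1767. The loss of the other 498 was thus not particular to WT replicate 2 and does not by itself point to that RNA.

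KO replicate 1 stood apart by genes that interferon gamma induces, a list that shares 2 genes with the interferon response list and 0 with the macrophage markers. Iigp1 had 24935 counts there against 1463 and 1126 in KO replicates 2 and 3 and 299 to 767 in WT, and the list's median lay 2.89 above the WT mean on the log2 scale. In KO replicate 1 against the other KO libraries, the list exceeded the macrophage markers, themselves 0.69 higher there, by 1.71 (bootstrap 95% interval 1.35 to 2.21). The list was written after these values were seen, so this excess was partly built in. It does not decide whether more macrophages alone are the source. The medians in KO replicates 3 and 2 were 0.29 and 0.50, above the WT libraries at -0.05 to 0.06, and 17 of 31 genes rose with all libraries, 7 of 32 without KO replicate 1 and 6 of 33 without WT replicate 2, so a smaller rise with the genotype may also be present. An infection or another inflammatory state of 1 sample stays open, and no biological explanation for it was tested, since the labels name none.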
